A study of Mus musculus with 12 samples.

How the data were processed

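Gene expression was measured on Affymetrix arrays in LSK cells, the fraction of mouse bone marrow that lacks lineage markers and carries SCA1 and cKIT and that is enriched for haematopoietic stem and progenitor cells. Donors were mice older than 20 months, backcrossed to C57BL/6 for at least 10 generations, with or without the gene for NIPA (Zc3hc1). Per the labels' protocols, cells of 3 mice were merged into each sample, kept for 30 min in medium with 30% fetal calf serum, 10 ng/ml IL-3, 10 ng/ml IL-6 and 50 ng/ml SCF, then irradiated with 4 Gy or left untreated and harvested after 3 h. RNA was extracted with a column kit for small samples, amplified with the Affymetrix WT Pico chemistry and labelled with biotin. The 12 arrays form 4 groups of 3: untreated wild type (WT), irradiated WT, untreated NIPA knockout (KO) and irradiated KO. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the untreated and irradiated samples of a genotype were parts of the same pools, so the p-values below measure the spread between these arrays.

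The values used were the authors' deposited log2 expression values, 1 per array and probe set. The submitters' processing notes name the R package oligo and RMA, a method that corrects background, normalizes across arrays by quantiles and summarises probes. Their versions, the genome build and the annotation release are not given in the sources used here, so no coordinates are printed. Array medians lay between 5.74 and 5.85 on the log2 scale. Correlation across the 15348 genes tested (chosen as described below), which are not independent replicates, was 0.960 to 0.986 within groups and 0.940 to 0.988 between groups. No arrays of a group were alike enough to be copies of each other. An array's precision is limited here by the number of arrays and not by a read depth.

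Probe sets were named through the platform annotation, which gave a symbol for 25335 of the 41345. Exactly 1 symbol was given for 23521 and several for 1814, while 16010 were without a symbol. Gene IDs of 23328 of the 23521 matched the RefSeq gene table of the mouse, through which symbols were updated. Of 22180 genes with such a probe set, 1082 had more than 1, and the brightest over the 12 arrays was used. Genes were tested if their value exceeded the 40th percentile of the whole table (5.29) in at least 3 arrays. This left 15348 genes and removed 6832. Zc3hc1 is measured by 1 probe set. Which part of the gene is missing in the knockout is not given in the sources used here. Every column of the table belonged to 1 of the 12 samples.

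Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in a single fit over all 12 arrays, so that the 4 groups share 1 estimate of the spread per gene. Contrasts were the irradiation effect in each genotype, the genotype effect at each dose, the difference of the irradiation effects (the interaction) and the averages of the irradiation and of the genotype contrasts. All p-values are two-sided and adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The median standard error of a log2 fold change was 0.147 for the simple contrasts, 0.207 for the interaction and 0.104 for the averages, which gives median half-widths of the 95% confidence interval of 0.319, 0.450 and 0.225. An exact permutation test of 3 arrays against 3 cannot go below p = 0.1, so single genes were judged by limma only.

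Gene groups were 30 lists written from textbook knowledge, 20 for processes and 10 for cell types that the sort could hold. They have 692 distinct members, of which 596 were tested, 26 fell below the brightness limit, 31 are measured only by probe sets with several symbols and 39 had no named probe set here. Each list was tested against the other genes with limma's camera, with a preset correlation of 0.01 between genes. Beside it stand camera with the correlation estimated for each list and fry, whose directional p asks whether a list's genes move on balance in 1 direction without comparing them with other genes. List p-values were adjusted over the 30 lists of a contrast. Members past the gene test are counted over all genes tested and adjusted over the list alone.

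The design, the tests, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule names Zc3hc1, Fancd2 and Ccnb1, the 8 largest rises and 8 largest falls of each simple contrast among genes past the test whose groups do not overlap, up to 4 members of each called list by smallest p, up to 2 passing members of other lists, 8 classical p53 targets and the 5 largest rises and falls of the average contrasts. Predicted genes are counted but not named. The script at first also left out microRNA, LOC and clone names, which the rule does not. This was corrected after the values were seen, and in KO cells Mir34a then took the place of Eda2r among the rises. For a contrast with no passing gene the rule names the 3 smallest p in each direction. Ccnb1 and Bax are measured only by probe sets with several symbols and are not analysed here. Where the rule gave more members of a list than the text prints, those whose call held with every single array left out were preferred, a choice made after the values were seen.

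The fit was tested on simulated data in which 50 genes per size were changed among the 15348. For the WT irradiation contrast it recovered 24% of changes of 0.5 on the log2 scale, 78% of those of 1 and 96% of those of 2. For the interaction it recovered 2% of changes of 0.5, 60% of those of 1 and 92% of those of 2, and for the genotype effect in untreated cells 28%, 76% and 94%. Unchanged genes that were called numbered 11, 10 and 7 in these contrasts and 15 for the genotype effect in irradiated cells, the highest of all contrasts. In simulated lists of 25 genes for the WT irradiation contrast, all 10 lists shifted by 0.5 were called and 0 of the 20 others. The noise of these genes was drawn independently, so this does not test lists whose genes vary together between arrays.

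Alternatives changed 1 choice at a time: no brightness limit or the 60th percentile (6.38), subtraction of array medians, cyclic loess between arrays, a trended and robust variance prior, array weights, the replicate number as a block, the mean over all probe sets of a gene, probe sets with several symbols kept under the first, an adjusted p of 0.1, a fold of at least 1.5, only the arrays of the groups compared, and each array left out in turn. Leaving out the irradiated arrays numbered 1, leaving out untreated KO array 2 with irradiated KO array 3, and the list tests with the number as a block within genotype or with array medians subtracted were added after the data had been seen. Subtracting array medians moved the median log2 change of all genes by at most 0.061, under 0.1, in every contrast.

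Whether shared replicate numbers pair the samples was checked through the correlation, across genes, of deviations from the group means. In WT, arrays with the same number correlated between the untreated and irradiated groups with r = 0.42 to 0.49, and the untreated WT and KO arrays with r = 0.10 to 0.23. All 3 pairs were over the limit of 0.1 in both comparisons, so the numbers were taken to pair the samples there, from the data and not from a statement in the labels. Between the untreated groups this hint is weak, since arrays with different numbers correlated as much (WT array 1 with KO array 3 at 0.14 and WT array 3 with KO array 2 at 0.13, against 0.10 for the arrays numbered 3). Every comparison was also repeated on other splits of the same arrays, all 10 splits of 3 against 3 or 100 drawn at random.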

Results

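The arrays describe how LSK cells of aged mice respond to 4 Gy of ionizing radiation within 3 h, and whether the response or the resting state differs without NIPA, an F-box-like protein known for its part in the ubiquitination of cyclin B1 and linked to the Fanconi anaemia protein FANCD2. Each of the 4 groups, WT and KO with and without irradiation, holds 3 arrays, and each array holds the cells of 3 mice. Over the 15348 genes tested, the first principal component held 41.7% of the variance and parted the 6 irradiated arrays from the 6 untreated ones. Component 2, with 17.4%, did not part the genotypes.

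**Figure D1:**
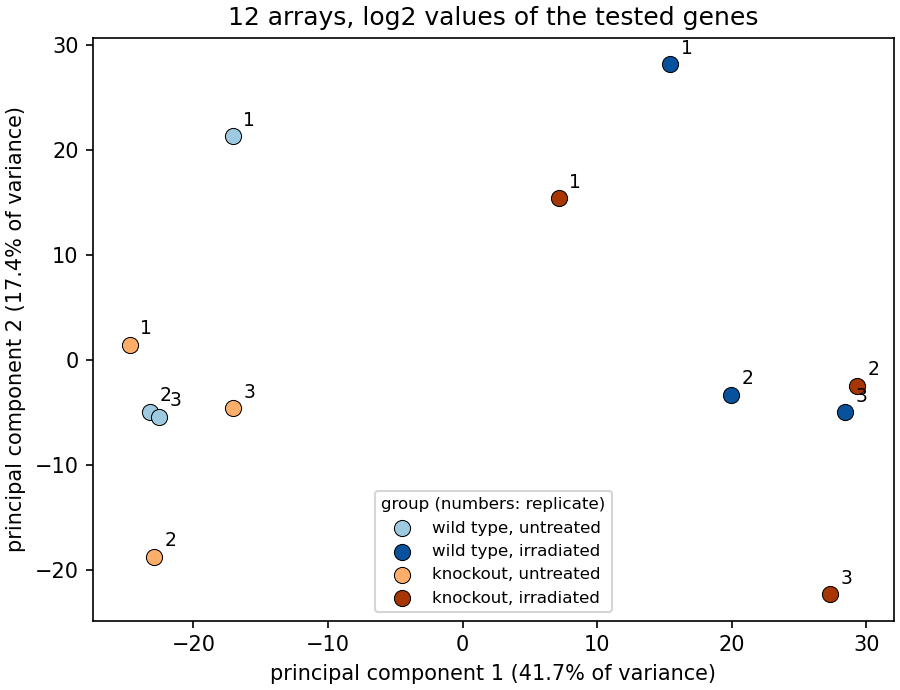
Principal components 1 and 2 of the 12 arrays over the 15348 genes tested (log2 values, component scores without unit), with colours for the 4 groups and numbers for the replicates. Component 1 (41.7% of the variance) lies between -24.7 and -17.1 in the untreated arrays and between 7.13 and 29.3 in the irradiated ones, and component 2 (17.4%) spreads the arrays within each group.

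Zc3hc1, the gene of NIPA, was low in all 6 KO arrays. Its log2 values were 8.47, 8.39 and 7.99 in untreated WT cells, 7.98, 8.21 and 7.67 in irradiated WT cells, 5.82, 5.74 and 5.78 in untreated KO cells and 5.61, 5.65 and 5.75 in irradiated KO cells. Group means were 8.29 ± 0.26, 7.95 ± 0.27, 5.78 ± 0.04 and 5.67 ± 0.07 (SD, n = 3). The KO level is close to the medians of whole arrays. Zc3hc1 differed by -2.50 (SE 0.15, limma adjusted p = 1.4e-05, a 5.67-fold difference) without irradiation and by -2.28 (SE 0.15, adjusted p = 4.0e-05) after it. Irradiation itself gave differences for Zc3hc1 of -0.33 in WT (adjusted p = 0.245) and -0.11 in KO cells (adjusted p = 0.751).

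**Figure D2:**
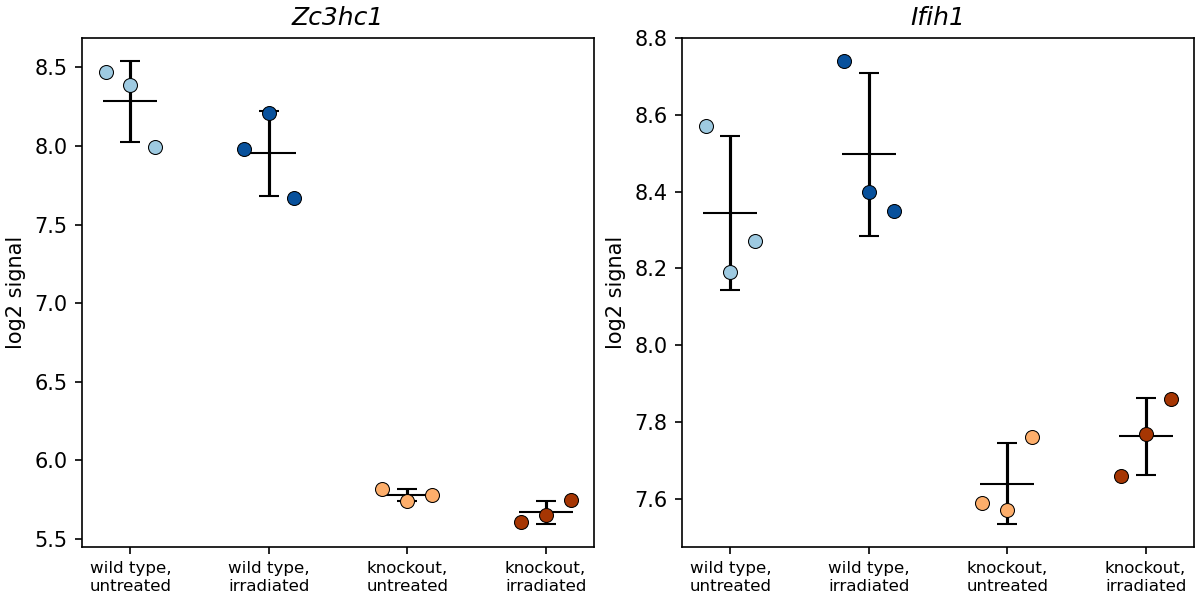
Log2 expression of Zc3hc1 and of Ifih1, a sensor of viral RNA, in each of the 12 arrays (points), with the group mean and SD (line and bars, n = 3). For Zc3hc1 all KO arrays lie between 5.61 and 5.82 and all WT arrays between 7.67 and 8.47, and for Ifih1 the KO arrays lie between 7.57 and 7.86 and the WT arrays between 8.19 and 8.74.

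In irradiated WT cells, genes that p53 activates rose and genes of mitosis fell within 3 h. Of the 38 p53 targets tested, 29 rose and 0 fell (34 rose adjusted over the list alone), with a median log2 change of 1.52. All 29 tested genes of the G2/M and mitosis list fell (29 adjusted over the list alone), with a median of -1.48. The p53 targets named in advance all rose: Cdkn1a, an inhibitor of cyclin-dependent kinases, by 1.26 (SE 0.23, limma adjusted p = 0.0079), Mdm2, the ubiquitin ligase of p53, by 1.60, Ccng1 by 1.90, Phlda3 by 2.78, Sesn2 by 1.70, Zmat3 by 1.54 and the pro-apoptotic Bbc3, which encodes PUMA, by 1.07 (n = 3 per group). Dcxr rose by 2.51 and Psrc1 by 2.16.

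The largest rises in WT cells were those of Fat1, an atypical cadherin, at 3.38 (SE 0.35, limma adjusted p = 0.00022), Tnfsf4, the OX40 ligand, at 3.31 (SE 0.53), Slc4a11 at 2.99 (SE 0.18), Cpt1c at 2.83, Phlda3 at 2.78, Eda2r and Epha2 at 2.69 each and Tnfrsf10b, a receptor of the death ligand TRAIL, at 2.64. Falls were largest for Prr11 at -2.98 (SE 0.32), the mitotic kinase Plk1 at -2.57 (SE 0.30, adjusted p = 0.0004), Car1, a carbonic anhydrase of red cell precursors, at -2.24 (SE 0.27), Cdk1, the kinase that drives entry into mitosis, at -2.14, Birc5 at -2.08, Depdc1a at -2.06 and Aurkb at -2.05. Ccna2 was also among the 8 largest falls. Other mitotic genes among the falls were Ttk, a kinase of the spindle checkpoint (-1.81), Hmmr (-1.98) and Sgo1, a protector of sister chromatid cohesion (-1.52).

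Some NF-kB and immediate early genes also rose in irradiated WT cells. Of 24 NF-kB and inflammation genes, 9 rose and 0 fell (15 rose adjusted over the list alone, median 0.51), among them Nfkb2 by 0.91 (SE 0.13), Nfkbia, the inhibitor that NF-kB itself induces, by 0.72, the growth factor Csf1 by 1.80 and the chemokine Cxcl2 by 1.30. Of 29 immediate early genes, 5 rose (10 rose and 1 fell adjusted over the list alone, median 0.28), with Ier5 at 1.21, the nuclear receptor Nr4a3 at 1.17 and Atf3 at 1.00. Camera gave adjusted p = 6.5e-39 for the p53 targets, 5.3e-37 for G2/M, 3.5e-11 for NF-kB and 5.2e-06 for the immediate early list. With an estimated correlation the calls of the p53 list (adjusted p = 0.0035) and of the NF-kB list (adjusted p = 0.022) held. The others were lost, with adjusted p = 0.093 with an estimated correlation for G2/M and 0.26 for the immediate early list. Fry, which does not compare a list with other genes, called 11 of the 30 lists in WT cells.

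Some genes of DNA repair and replication fell after irradiation in WT cells, and the calls of their lists were lost with an estimated correlation. Fancd2, the central protein of the Fanconi anaemia pathway, fell by 0.94 (SE 0.13, limma adjusted p = 0.0016) and Fanci, its partner, by 0.71, in a list of 25 of which 6 fell (11 adjusted over the list alone, median -0.30, camera adjusted p = 4.9e-07, adjusted p = 0.093 with an estimated correlation). Of 19 homologous recombination genes, 6 fell (10 adjusted over the list alone, median -0.52), including the kinase Atm (-0.74) and the nuclease Exo1 (-1.01), with adjusted p = 3.5e-08 and adjusted p = 0.22 with an estimated correlation. The end joining genes Rif1 (-0.65) and Xrcc6, which encodes KU70 (-0.93), were the 2 of 15 that fell (4 adjusted over the list alone, median -0.19, adjusted p = 0.0031, adjusted p = 0.22 with an estimated correlation). Of 29 G1/S and replication genes, 4 fell (19 adjusted over the list alone, median -0.50, adjusted p = 2.2e-12), with Tyms, the thymidylate synthase, at -0.75, and the list's adjusted p = 0.23 with an estimated correlation. Some of these calls were lost with single arrays left out or with other processing. Fanci had adjusted p = 0.063 without untreated WT array 2 and 0.069 without untreated WT array 3. For Rif1 the adjusted p was 0.089 without untreated WT array 2, 0.18 without 3, 0.12, 0.075 and 0.065 without irradiated WT arrays 1, 2 and 3, 0.062, 0.061 and 0.061 without untreated KO arrays 1, 2 and 3 and 0.054 without irradiated KO array 3. For Xrcc6 it was 0.18 and 0.15 without untreated WT arrays 2 and 3, 0.10, 0.088 and 0.13 without irradiated WT arrays 1, 2 and 3 and 0.060 without untreated KO array 1. Rif1 and Xrcc6 also lost their calls without a brightness limit (adjusted p = 0.050 and 0.055), after subtraction of array medians (0.076 and 0.056) and after cyclic loess (0.082 and 0.060). With only the WT arrays in the fit Rif1 had 0.066, and with the replicate block within genotype, which pairs the WT arrays, Xrcc6 had 0.054.

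Among metabolic and biosynthetic lists in WT cells, 7 of 28 ribosome biogenesis genes fell and 1 rose (15 and 1 adjusted over the list alone, median -0.44, camera adjusted p = 4.0e-09, adjusted p = 0.26 with an estimated correlation), with Rrp12 at -0.74. Cholesterol synthesis had 2 of 17 genes that rose (6 adjusted over the list alone, median 0.31, adjusted p = 0.00036, adjusted p = 0.22 with an estimated correlation), Fdft1, the squalene synthase, by 0.48 and Msmo1 by 0.40. Of 28 oxidative phosphorylation genes, 1 fell, Atp5o at -0.42 (1 adjusted over the list alone, median -0.26, adjusted p = 0.00045, adjusted p = 0.67 with an estimated correlation). The antioxidant list had a median of 0.62 over 19 genes, of which 1 rose, Hmox1, the haem oxygenase, by 2.03 (SE 0.49, limma adjusted p = 0.034). Adjusted over the list alone 3 rose and 2 fell, the camera adjusted p was 0.0031, and adjusted p = 0.40 with an estimated correlation. Slc7a11, the cystine transporter, had 2.22 (SE 0.68, adjusted p = 0.088) and Srxn1 1.63 (adjusted p = 0.070). The mean score of this list over WT untreated cells was 0.19 in irradiated WT array 1 against 1.03 and 0.91 in arrays 2 and 3.

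Some of these calls were lost when single arrays were left out, which also leaves fewer arrays for the test. Hmox1 had adjusted p = 0.057 and 0.15 without untreated WT arrays 1 and 3 and 0.085 and 0.14 without irradiated WT arrays 2 and 3, the antioxidant list 0.066 without irradiated WT array 2 (median 0.39). The oxidative phosphorylation list had 0.071 without irradiated WT array 3 (median -0.10). Fdft1 lost its call without untreated WT array 2 (adjusted p = 0.062) or 3 (0.096) and without irradiated WT array 1 (0.057), 2 (0.051) or 3 (0.057). Atp5o lost its call without any of the 12 arrays except irradiated WT array 1 and irradiated KO array 1, with adjusted p of up to 0.12 without untreated WT array 2. Msmo1 lost it without any array except irradiated KO array 1, with adjusted p of up to 0.17 without irradiated WT array 3. Atp5o also lost its call after subtraction of array medians (0.098) and with only the WT arrays (0.11), Msmo1 with the replicate block within genotype (0.066) and with only the WT arrays (0.11), and Hmox1 with the trended and robust prior (0.053).

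Among markers of other cell types in WT cells, Car1 was the 1 of 11 erythroid genes that fell (6 fell adjusted over the list alone, median -0.42, camera adjusted p = 0.0031, adjusted p = 0.22 with an estimated correlation). In the lymphoid-primed list of 9 genes, the cytokine receptor Flt3 fell by 1.30 (SE 0.16, limma adjusted p = 0.00058) and Satb1 by 0.70 (3 fell and 1 rose adjusted over the list alone, median -0.41, adjusted p = 0.033, adjusted p = 0.53 with an estimated correlation). This list's call was lost with the replicate number as a block (adjusted p = 0.058), without untreated WT array 2 (0.11) or 3 (0.064), irradiated WT array 1 (0.060) or 2 (0.051) and irradiated KO array 1 (0.051). Satb1 had adjusted p over 0.05 without untreated WT array 2 (0.18) or 3 (0.18), irradiated WT array 1 (0.11), 2 (0.051) or 3 (0.13), and untreated KO array 1 (0.063), 2 (0.062) or 3 (0.061). It also lost its call without a brightness limit (0.052), after subtraction of array medians (0.057), after cyclic loess (0.057) and with only the WT arrays in the fit (0.066).

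The remaining 16 lists were not called in WT cells. Their medians and camera adjusted p were 0.20 and 0.13 for aged stem cell genes, 0.14 and 0.16 for quiescence and cell cycle inhibitors, -0.09 and 0.20 for haematopoietic stem cell genes, -0.02 and 0.40 for plasmacytoid and dendritic markers. They were -0.08 and 0.43 for cell death machinery, 0.04 and 0.45 for hypoxia and glycolysis and 0.11 and 0.45 for megakaryocyte markers. For the interferon response they were -0.09 and 0.67, for T and NK cell 0.06 and 0.73, for B cell -0.09 and 0.73, for heat shock 0.07 and 0.73. For monocyte and macrophage markers they were -0.02 and 0.77, for the unfolded protein and integrated stress response 0.03 and 0.90, for mast cell and basophil -0.02 and 0.97, for endothelial and stromal 0.03 and 0.97 and for granulocyte markers 0.09 and 0.97. The T and NK cell, mast cell, endothelial and granulocyte lists had a median and a mean of opposite sign. Genes past the test in these lists included Tob1, an anti-proliferative protein, which rose by 1.44, Rbl1, the retinoblastoma relative p107, which fell by 1.00, Adm, which rose by 1.55, and Ddit4, an inhibitor of mTOR signalling, which rose by 0.97. Under the replicate block within genotype the aged stem cell list was called (adjusted p = 0.047).

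In WT cells 742 of 15348 genes passed the limma test, 327 higher and 415 lower, and 3040 had an unadjusted p under 0.05. The arrays of the groups did not overlap in 741 of the 742 and in 24.8% of all genes, where chance gives 10%. The split by direction depended on the scaling, with 44.1% of the calls higher in the deposited values, 54.6% (418 higher and 347 lower) after subtraction of array medians and 51.4% (389 and 368) after cyclic loess. No named gene with a call turned direction under either, and no called list of the simple contrasts or the interaction did. With the replicate number as a block within genotype, the pairing that the WT arrays show, 1228 genes passed, 717 of them among the 742. The count fell to 337 without untreated WT array 2, 314 without untreated WT array 3 and 350 without irradiated WT array 3. It was 1147 when the irradiated arrays numbered 1 of both genotypes were left out.

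In irradiated KO cells p53 targets likewise rose and mitosis genes fell. Of 38 p53 targets, 30 rose and 0 fell (34 rose and 1 fell adjusted over the list alone, median 1.55), among them Cdkn1a by 1.31 (SE 0.23, limma adjusted p = 0.0053), Mdm2 by 1.67, Ccng1 by 1.93, Phlda3 by 2.78, Sesn2 by 1.77, Zmat3 by 1.40, Dcxr by 2.47, Psrc1 by 2.02 and Bbc3 by 0.95 (n = 3 per group). Of 29 G2/M and mitosis genes, 25 fell (29 adjusted over the list alone, median -1.33), with Plk1 at -2.34 (SE 0.30), Birc5 at -2.01, Cdk1 at -1.95, Nuf2 and Ska1, proteins of the kinetochore, at -1.87 and -1.78, Hmmr at -1.73, Ttk at -1.61 and Sgo1 at -1.57. Bbc3 had adjusted p = 0.073 and 0.055 without untreated KO arrays 2 and 3 and 0.066 without irradiated KO array 2.

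The largest rises in KO cells were those of Tnfsf4 (3.61, SE 0.53, limma adjusted p = 0.0020), Fat1 (3.29), Slc4a11 (3.09), Tnfrsf10b (2.90), Mir34a, the host of a microRNA that p53 induces (2.80, SE 0.65, adjusted p = 0.024), Cd80, a costimulatory ligand of T cells (2.79), Epha2 (2.79) and Phlda3 (2.78). Mir34a had adjusted p over 0.05 with only the arrays compared (0.066) and without untreated KO array 1 (0.088), 2 (0.070) or 3 (0.063) or irradiated KO array 2 (0.090) or 3 (0.087). Car1 had the largest fall, -3.16 (SE 0.27, adjusted p = 4.6e-05), and Prr11 and Depdc1a had -2.31 and -2.07. Car1 belongs to the erythroid list, in which 4 of 11 genes fell (8 adjusted over the list alone, median -0.51, camera adjusted p = 2.0e-05, adjusted p = 0.088 with an estimated correlation). The blood group protein Ermap fell by 1.46 and Rhag, an ammonium channel of the red cell membrane, by 1.00.

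Of 24 NF-kB and inflammation genes in KO cells, 14 rose (16 adjusted over the list alone, median 0.77), including Nfkbia by 1.07 (SE 0.11, limma adjusted p = 0.00015), Nfkb2 by 1.15, Csf1 by 2.27 and Relb by 1.03. Immediate early genes had 9 of 29 that rose (11 rose and 1 fell adjusted over the list alone, median 0.37), with Nr4a3 at 1.55, Gadd45b at 1.26, Atf3 at 1.06 and Ier5 at 1.02. Camera gave adjusted p = 9.1e-42 for p53 targets, 6.5e-30 for G2/M, 5.8e-14 for NF-kB and 2.0e-08 for immediate early genes. The p53 (adjusted p = 0.0027) and NF-kB calls (adjusted p = 0.010) held with an estimated correlation. The others were lost, with adjusted p = 0.090 with an estimated correlation for G2/M and 0.19 for immediate early genes. Fry called 11 of the 30 lists in KO cells.

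Some DNA repair genes also fell in irradiated KO cells, with list calls that were lost with an estimated correlation. Fancd2 fell by 1.02 (SE 0.13, limma adjusted p = 0.00097), Fanci by 0.82 and Fancb by 0.76, and in all 7 of 25 Fanconi genes fell (13 adjusted over the list alone, median -0.37, camera adjusted p = 5.5e-08, adjusted p = 0.067 with an estimated correlation). Of 19 homologous recombination genes, 9 fell (14 adjusted over the list alone, median -0.61, adjusted p = 9.2e-10, adjusted p = 0.16 with an estimated correlation), with Atm at -0.97 and the helicase Blm at -0.71. End joining had 2 of 15 genes that fell (6 fell and 1 rose adjusted over the list alone, median -0.24, adjusted p = 0.0056, adjusted p = 0.23 with an estimated correlation), Rif1 at -0.75 and Xrcc6 at -1.08. G1/S and replication had 9 of 29 (13 adjusted over the list alone, median -0.46, adjusted p = 3.9e-10, adjusted p = 0.27 with an estimated correlation), with Tyms at -0.75. Rif1 lost its call without untreated KO array 1 (adjusted p = 0.060), 2 (0.080) or 3 (0.052) and irradiated KO array 3 (0.055). Xrcc6 lost it without untreated KO array 2 (0.059) or irradiated KO array 2 (0.086), and with only the KO arrays in the fit (0.078).

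Cholesterol synthesis genes rose in 6 of 17 cases in KO cells (10 adjusted over the list alone, median 0.40, camera adjusted p = 3.1e-08, adjusted p = 0.064 with an estimated correlation), with the demethylase Cyp51 at 0.95 (SE 0.16, limma adjusted p = 0.0048), Msmo1 at 0.67 and Fdft1 at 0.60. Of 28 ribosome biogenesis genes, 5 fell (12 fell and 1 rose adjusted over the list alone, median -0.37, adjusted p = 5.0e-07, adjusted p = 0.35 with an estimated correlation). The antioxidant list had 2 of 19 genes that rose (8 rose and 2 fell adjusted over the list alone, median 0.67, adjusted p = 0.00015, adjusted p = 0.27 with an estimated correlation), Hmox1 by 2.42 and Fth1, the ferritin heavy chain, by 0.62. Its score was 0.30 in irradiated KO array 1 against 1.01 and 0.99 in arrays 2 and 3. Hmox1 had adjusted p = 0.060 without untreated KO array 1 and 0.061 and 0.055 without irradiated KO arrays 2 and 3. Fth1 had 0.14 and 0.11 without untreated KO arrays 1 and 3 and 0.13 and 0.12 without irradiated KO arrays 2 and 3, as well as 0.077 with only the KO arrays in the fit.

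With 0 passing members, over all genes or adjusted over the list alone, the aged stem cell list had a median of 0.26 (camera adjusted p = 0.0066, adjusted p = 0.69 with an estimated correlation) and the heat shock list 0.30 (adjusted p = 0.034, adjusted p = 0.49 with an estimated correlation). The aged stem cell call was lost without untreated KO array 2 (adjusted p = 0.16) or irradiated KO array 2 (0.23). The heat shock call was lost without untreated KO array 2 (0.050) or 3 (0.12) or irradiated KO array 2 (0.051) or 3 (0.070). The other 16 lists were not called in KO cells, with adjusted p from 0.069 for the unfolded protein and integrated stress response and 0.099 for oxidative phosphorylation to 1.0 for B cell markers. Among their members Tob1 rose by 1.75, Adm by 1.62, Ddit4 by 1.03 and the interferon-induced Mx2 by 0.73, while Rbl1 fell by 1.00 and Flt3 by 0.96. B cell markers stood high in untreated KO array 2 and irradiated KO array 3, with list scores of 1.16 and 1.22 against -0.16 to 0.09 in the other KO arrays.

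In KO cells 911 of 15348 genes passed the limma test, 420 higher and 491 lower, with 3055 at an unadjusted p under 0.05. The balance of directions depended on the scaling, with 490 higher and 419 lower after subtraction of array medians and 489 and 424 after cyclic loess. All 911 had groups that did not overlap, as had 23.4% of all genes, where chance gives 10%. The count was 483 and 392 without untreated KO arrays 1 and 2, 1573, 468 and 533 without irradiated KO arrays 1, 2 and 3, 1702 without the irradiated arrays numbered 1, and 283 without the arrays with high B cell markers.

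**Figure D3:**
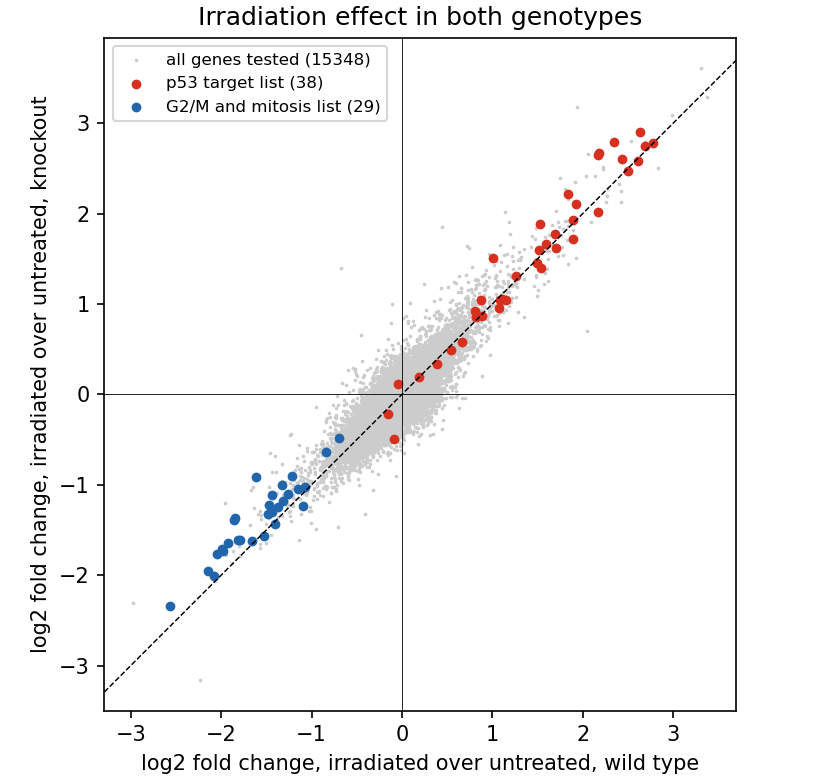
Log2 fold change 3 h after 4 Gy in WT cells (horizontal) against KO cells (vertical) for the 15348 genes tested (grey), the 38 p53 targets (red) and the 29 G2/M genes (blue), with the line of equal change dashed. Across genes, which are not independent replicates, r was 0.864, and the medians of p53 targets (1.52 and 1.55) and of G2/M genes (-1.48 and -1.33) lie near the line.

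Genes called after irradiation moved the same way in WT and KO cells, with few exceptions. Both contrasts called 550 genes, 264 higher and 286 lower and 0 in opposite directions, where independent lists of these lengths would share 8.95 and 13.3. The contrasts use no array in common. Another 192 genes passed in WT only and 361 in KO only, and of the 1103 genes called in either, 1098 (99.5%) had the same sign in both, with a slope of 0.996 of KO on WT changes. Over all 15348 genes, which are not independent replicates, 74.5% had the same sign and the correlation of the fold changes was 0.864. Whether a gene called in a single genotype differs between them is what the interaction tests.

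The interaction asks whether the response to irradiation depends on NIPA, and no gene passed it in a fit that does not pair the arrays. The limma count was 0, with 235 of 15348 genes at an unadjusted p under 0.05. The smallest p among genes with a more positive response in KO cells belonged to Slc35d2 (0.65, SE 0.13), Hmgn5 (0.72, SE 0.16) and A1cf (0.88, SE 0.22), and among those with a more negative one to Igf2 (-0.58, SE 0.13), Gsc2 (-0.65, SE 0.16) and Kif26a (-0.59, SE 0.15). None of these passed. Zc3hc1 had 0.22 (SE 0.21) and Fancd2 -0.07 (SE 0.19). The median 95% half-width of 0.450 leaves room for differences of that size, and in simulated data 60% of differences of 1 were recovered.

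Camera called 9 lists in the interaction, with 0 passing members in each, over all genes or adjusted over the list alone, and with 0 calls both with an estimated correlation (smallest adjusted p = 0.58) and by fry (adjusted p = 0.96). The median over 29 G2/M genes was 0.19 (adjusted p = 0.0034, adjusted p = 0.80 with an estimated correlation), with Prc1 at 0.48 (SE 0.34) and Bub1b at 0.33. Over 17 cholesterol synthesis genes it was 0.11 (adjusted p = 0.0034, adjusted p = 0.58 with an estimated correlation), with Sc5d at 0.50 (SE 0.20). NF-kB genes had a median of 0.21 (Nfkbia 0.36), erythroid genes -0.25 (Car1 -0.92, SE 0.38) and interferon genes 0.12 (Irf7 0.49, SE 0.22), each with adjusted p = 0.0082 and adjusted p of 0.58, 0.58 and 0.80 with an estimated correlation. The unfolded protein and integrated stress response (0.11, Herpud1 0.33) and oxidative phosphorylation (0.11, Atp5o 0.29) had adjusted p = 0.018, heat shock (0.15, Hsp90aa1 0.36) 0.024 and granulocyte markers (0.18, Gstm1 0.69) 0.035, all with adjusted p = 0.80 with an estimated correlation. The monocyte list had a median of -0.02 and a mean of 0.06.

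Each of the 9 interaction calls was lost when 1 array or another was left out. Without untreated WT array 2 the adjusted p was 0.28 for G2/M (median 0.05), 0.099 for cholesterol, erythroid, interferon and oxidative phosphorylation, 0.13 for the unfolded protein list, 0.15 for heat shock and 0.11 for granulocyte markers. Without irradiated WT array 1 it was 0.058 for G2/M, cholesterol and oxidative phosphorylation, 0.13 for erythroid, 0.69 for the unfolded protein list, 0.23 for heat shock and 0.95 for granulocyte markers (median -0.08). Without irradiated WT array 3 it was 0.082 for NF-kB, 0.37 for interferon, 0.93 for oxidative phosphorylation (-0.04) and 0.16 for heat shock. Without untreated WT array 1 NF-kB had 0.093, oxidative phosphorylation 0.13 and heat shock 0.081. Without untreated WT array 3 granulocyte markers had 0.69 (-0.08). Leaving out irradiated KO array 3, the array with high B cell markers, gave G2/M a median of -0.04 (adjusted p = 0.70), the unfolded protein list 0.40 and heat shock 0.15. Without untreated KO array 3 G2/M had 0.21, oxidative phosphorylation 0.12, the unfolded protein list 0.26, heat shock 0.12 and granulocyte markers 0.067. Granulocyte markers had a median of -0.05 (adjusted p = 0.66) and heat shock adjusted p = 0.052 without untreated KO array 2. Erythroid markers had 0.070 and heat shock 0.12 without irradiated KO array 2. Without irradiated KO array 1 interferon had 0.11, oxidative phosphorylation 0.89 (-0.05) and granulocyte markers 0.58 (-0.07). Without untreated KO array 1 monocyte markers were called at 0.25 (0.029). The number of lists called was 2 without untreated WT array 2, 4 without irradiated WT array 1, 5 without irradiated WT array 3, 14 without untreated KO array 2 and 5 without both arrays with high B cell markers.

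**Figure D4:**
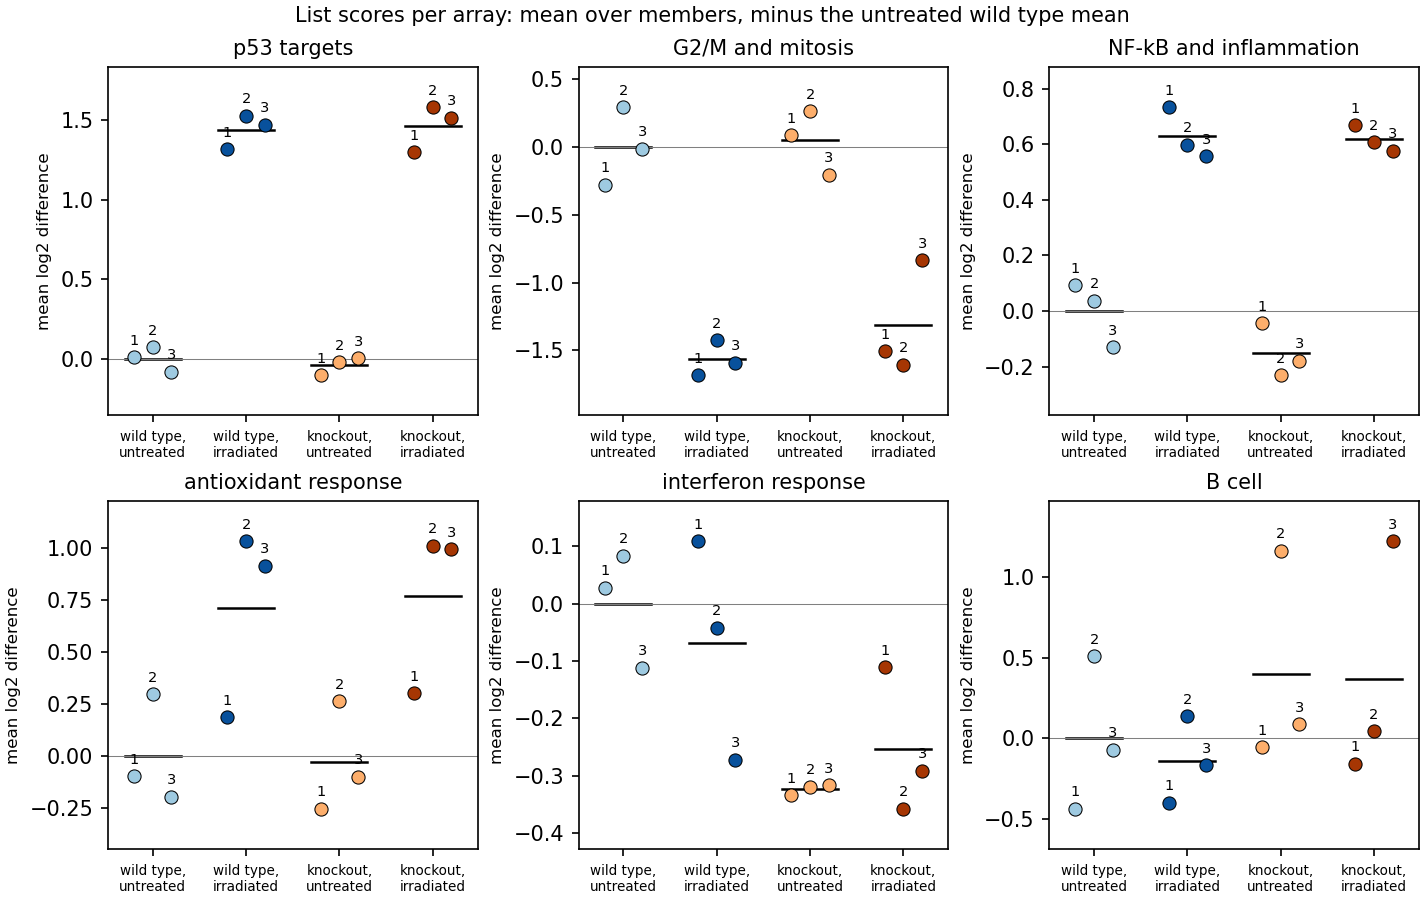
Scores of 6 gene lists in each array (points; mean log2 value over a list's tested members minus its mean in untreated WT cells), with lines for the group means. G2/M scores lie at -1.51, -1.60 and -0.83 in irradiated KO arrays 1, 2 and 3, antioxidant scores are lowest in the irradiated arrays numbered 1 (0.19 in WT and 0.30 in KO), and B cell scores are highest in untreated KO array 2 (1.16) and irradiated KO array 3 (1.22).

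Without irradiation, Zc3hc1 was the 1 gene past the limma test between KO and WT cells. In simulated data this contrast recovered 28% of changes of 0.5 and 76% of those of 1, so other differences may have been missed. The limma count was 1 of 15348, with 330 genes at an unadjusted p under 0.05, and 7.96% of all genes had groups that did not overlap, where chance gives 10%. Fancd2 differed by 0.03 (SE 0.13). Interferon response genes had the lowest list result, with a median of -0.30 over 29 genes, 25 of them below 0, and 0 that passed over all genes but 7 that fell adjusted over the list alone (camera adjusted p = 2.2e-15, adjusted p = 0.12 with an estimated correlation). Ifih1, a sensor of viral RNA, had -0.70 (SE 0.14), Mx2, an antiviral GTPase, -0.53 (SE 0.12), Rsad2, the antiviral viperin, -0.77 (SE 0.22) and Oasl1 -0.59 (SE 0.18). The call of the interferon list held with each array left out.

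In untreated cells another 9 lists were called by camera, and 0 of the 10 held with an estimated correlation or by fry. Cholesterol synthesis had a median of -0.19 (adjusted p = 5.2e-07, adjusted p = 0.12 with an estimated correlation), with Msmo1 at -0.24 and Cyp51 at -0.35. Erythroid markers had 0.19 (3 rose adjusted over the list alone, adjusted p = 0.00017, adjusted p = 0.18 with an estimated correlation), with Car1 at 1.16 (SE 0.27) and Rhag at 0.59. NF-kB genes had -0.12 (adjusted p = 0.00046, adjusted p = 0.19 with an estimated correlation), with Ccl5 at -0.98 (SE 0.27). Aged stem cell genes had -0.19 (adjusted p = 0.0010), oxidative phosphorylation -0.12 (0.0011), homologous recombination 0.11 (0.0020, 1 rose adjusted over the list alone, Atm at 0.59), haematopoietic stem cell genes -0.12 (0.013, Abcg2 at -0.47), B cell markers 0.43 (0.017, Pax5 at 0.72) and immediate early genes -0.08 (0.023, Dusp4 at -0.57), each with adjusted p = 0.65 with an estimated correlation. The other called lists had 0 members past the test when adjusted over the list alone. Untreated KO array 2 had a B cell score of 1.16, against -0.06 and 0.09 in untreated KO arrays 1 and 3 and -0.44, 0.51 and -0.07 in the untreated WT arrays. The other 20 lists had adjusted p of 0.071 or more, and the median and mean of p53 targets and T and NK cell markers differed in sign.

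Leaving out single arrays ended several of these calls. Without untreated WT array 1 the adjusted p was 0.88 for homologous recombination (-0.01), 0.89 for aged stem cell genes (0.02), 0.88 for immediate early genes (0.02), 0.19 for haematopoietic stem cell genes, 0.62 for B cell markers (0.16) and 0.060 for oxidative phosphorylation, and 5 lists were called. Without untreated KO array 2 it was 0.37 for homologous recombination (0.04), 0.37 for aged stem cell genes, 0.85 for immediate early genes (0.05), 0.52 for haematopoietic stem cell genes and 0.92 for B cell markers (0.01), and 6 lists were called. Haematopoietic stem cell genes had 0.11 and B cell markers 0.071 without untreated WT array 3, and haematopoietic stem cell genes 0.070 without untreated KO array 1. Further, 16 lists were called without untreated KO array 3. With the replicate number as a block, Zc3hc1 remained the 1 gene called, and end joining (0.09) and lymphoid-primed genes (0.15) were called too, both with adjusted p = 0.049. The hint that the numbers pair the untreated WT and KO arrays is weak, and the block also spans KO numbers 2 and 3, which do not match between the doses.

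After irradiation, Zc3hc1 was again the 1 gene past the limma test between KO and WT cells. Of 15348 genes 471 had an unadjusted p under 0.05, and 6.40% had groups without overlap, where chance gives 10%. Fancd2 differed by -0.05 (SE 0.13). G2/M genes had a median of 0.24 over 29 genes (camera adjusted p = 2.3e-06, adjusted p = 0.85 with an estimated correlation), with Bub1b at 0.33 (SE 0.17), Ccna2 at 0.54 (SE 0.28) and Mki67 at 0.56 (SE 0.30). Interferon genes had -0.13 (1 fell adjusted over the list alone, adjusted p = 0.00013, adjusted p = 0.73 with an estimated correlation), with Ifih1 at -0.74 (SE 0.14) and Isg15 at -0.57 (SE 0.20).

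Lymphoid-primed genes had a median of 0.42 in irradiated KO against WT cells (camera adjusted p = 0.00013, adjusted p = 0.73 with an estimated correlation), with Satb1 at 0.55 (SE 0.18). B cell markers had 0.49 (adjusted p = 0.0030, adjusted p = 0.85 with an estimated correlation), with Jchain at 1.19 (SE 0.52). The B cell score was 1.22 in irradiated KO array 3 and between -0.40 and 0.14 in the other 5 irradiated arrays. The same array had the highest G2/M score of the irradiated arrays, -0.83 against -1.42 or less. Ribosome biogenesis had 0.10 (adjusted p = 0.010, Heatr1 at 0.28), haematopoietic stem cell genes -0.12 (0.022, Tal1 at -0.35) and G1/S genes 0.08 (0.022, Cdc6 at 0.39), with adjusted p = 0.94 with an estimated correlation. The unfolded protein and integrated stress response had 0.11 (0.013, Herpud1 at 0.28, adjusted p = 0.85 with an estimated correlation) and mast cell and basophil markers 0.16 (0.022, Cpa3 at 0.90, SE 0.29, adjusted p = 0.73 with an estimated correlation). None of the 9 calls held with an estimated correlation or by fry, and among the called lists no member but that of the interferon list passed when adjusted over the list alone. The other 21 lists had adjusted p of 0.092 or more, and in 6 of them, T and NK cell, cell death, p53, endothelial, hypoxia and oxidative phosphorylation, the signs of median, mean and test differed.

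In irradiated cells 1 list was called without irradiated KO array 3 and 2 without irradiated WT array 1. Without irradiated KO array 3 the G2/M median was 0.02 (adjusted p = 0.92), the lymphoid-primed 0.28 (0.060), the B cell 0.10 (0.92), the G1/S median -0.005 (0.89). Adjusted p was 0.89 for haematopoietic stem cell genes, 0.17 for mast cell markers, 0.060 for ribosome biogenesis and 0.86 for the unfolded protein list. Without irradiated WT array 1 the interferon median was -0.07 (adjusted p = 0.13). Adjusted p was 0.13 for B cell, 0.29 for G1/S, 0.83 for haematopoietic stem cell, 0.25 for mast cell, 0.083 for ribosome biogenesis and 0.66 for the unfolded protein list. Without irradiated WT array 3 G1/S had 0.28 and ribosome biogenesis 0.13. Without irradiated KO array 1 ribosome biogenesis had a median of -0.02 (0.67), G1/S adjusted p = 0.12, haematopoietic stem cell genes 0.21 and mast cell markers 0.13.

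Averaged over the genotypes, 2532 of 15348 genes changed with irradiation by limma, 1059 higher and 1473 lower (41.8% higher), with 4625 at an unadjusted p under 0.05. The split was 1424 and 1194 (54.4% higher) after subtraction of array medians and 1280 and 1265 (50.3%) after cyclic loess. Rises were largest for Tnfsf4 at 3.46 (SE 0.37), Fat1 at 3.33, Slc4a11 at 3.04, Phlda3 at 2.78 and Tnfrsf10b at 2.77, and falls for Car1 at -2.70 (SE 0.19), Prr11 at -2.64, Plk1 at -2.45, Depdc1a at -2.07 and Cdk1 at -2.05. In this contrast 34 of 38 p53 targets rose, while 29 of 29 G2/M genes, 19 of 29 G1/S genes, 14 of 19 homologous recombination genes and 14 of 25 Fanconi genes fell. Of 24 NF-kB genes 15 rose, and of 19 antioxidant genes 8 rose and 1 fell (adjusted over the list alone 35, 29, 25, 16, 18, 15 and 12, with 1 p53 target and 3 antioxidant genes that fell). Camera's adjusted p with an estimated correlation was 0.0044 for p53 targets and 0.014 for NF-kB and 0.087 or more for the rest. By fry, 13 of the 30 lists were called.

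Averaged over the doses, Zc3hc1 at -2.39 (SE 0.11, limma adjusted p = 3.7e-07) was the 1 gene that passed between genotypes, with 635 of 15348 genes at an unadjusted p under 0.05. Ifih1 had -0.72 and adjusted p = 0.052, lower in 6 of 6 KO arrays than in any WT array. Ifih1 was named after its values were seen. The fit counts the arrays as independent, although arrays of both doses may share pools, which would leave 3 pools per genotype. The p-values of this contrast and the count of arrays may then overstate the evidence. Over 23 alternatives Ifih1 ranged from -0.76 to -0.63 with adjusted p from 0.041 to 0.54 and passed in 4 of them, and Zc3hc1 passed in all 23. The interferon list had a median of -0.23 over 29 genes (6 fell adjusted over the list alone, camera adjusted p = 1.4e-13, adjusted p = 0.18 with an estimated correlation), and the call held with each of the 12 arrays left out. Across all genes, which are not independent replicates, the genotype differences with and without irradiation correlated with r = 0.376, and 56.4% had the same sign. Pools shared by both doses could raise this correlation.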

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

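The tests that weigh explanations for the G2/M, interferon and antioxidant differences were chosen only after the results were seen, while the counts of other splits and the split test of the interferon list were planned. A test of the difference between the irradiation effects of KO and WT cells singled out 9 lists, whose camera calls were not kept with an estimated correlation. G2/M genes such as Plk1 and Cdk1 had a median difference of 0.19. The cholesterol synthesis list had a median difference of 0.11 between the responses. For NF-kB and inflammation genes the difference was 0.21. Erythroid markers differed by -0.25. In the interferon response list the difference was 0.12. Genes of the unfolded protein and integrated stress response differed by 0.11. Oxidative phosphorylation genes had a median difference of 0.11. Heat shock genes showed 0.15. Granulocyte markers had 0.18. Of 100 splits of the arrays, 49 called as many lists, 18 at the highest against the real 9, so chance cannot be excluded for the number of lists. For genes the real count was 0, which all 100 splits reach by construction (22 at the highest), so that count says nothing about chance.

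Outside the named genes, probe sets with several symbols also carried a signal of irradiation, and those without a symbol hardly any. Among probe sets without a symbol, 5 passed the limma test in WT cells (1 higher, 4 lower) and 1 in KO cells, of 8974 tested (0.056% and 0.011%). Among those with several symbols, 21 passed in WT cells (10 higher, 11 lower) and 32 in KO cells (12 higher, 20 lower), of 1164 tested (1.8% and 2.7%). In the genotype comparisons the limma count was 0 for both kinds.

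Other splits of the same arrays bear on the counts of genes and lists. For irradiation averaged over the genotypes 1 of 100 splits, the real one, gave as many genes (2532, highest other 682). Chance is argued against for that gene count if the arrays are independent. Arrays of both doses may share pools, and splits that only exchange doses within shared pools were not examined on their own for this average. The 14 lists called there were matched by 34 of 100 splits (highest other 19), so chance cannot be excluded for the number of lists. Within a genotype the 10 splits are too few for a share under 0.05: the real split gave 742 genes in WT (1 of 10, highest other 0) and 911 in KO cells (1 of 10, highest other 0). It gave 14 lists in WT (4 of 10, highest other 16) and 14 in KO (3 of 10, highest other 17). In WT, where the numbers pair the arrays, the splits that part all 3 pairs and those that part fewer both had 0 genes at the highest. For genotype the splits are too few as well, with 1 gene without irradiation (1 of 10, highest other 0), 10 lists (7 of 10, highest other 19), 1 gene after irradiation (2 of 10, highest other 86) and 9 lists (6 of 10, highest other 12). For genotype averaged over the doses, 6 of 100 splits gave as many genes as the real 1 (highest other 793). For lists, 9 of 100 gave as many as the real 15 (highest other 18), so chance cannot be excluded for either count. The split with 793 genes sets WT arrays 1 and 2 and KO array 1 of both doses against the rest. The split with 86 genes does so among irradiated arrays. This points to a structure of the samples beyond genotype.

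The G2/M list had a median difference of 0.19 between the responses of KO and WT cells, with 0 genes past the test and adjusted p = 0.80 with an estimated correlation. Without irradiated KO array 3 the difference was -0.040, so the pattern may rest on that array. The B cell score of the array was 1.22, and B-lineage cells that divide may have been in its pool, although the sort removed cells with B220. Untreated KO array 2, which also had high B cell markers, had a G2/M score 0.32 above the other untreated KO arrays. That lies within the range of the untreated WT arrays, so this source cannot be told apart from spread between samples. An effect of NIPA on mitotic genes stays open and untested beyond these values.

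The interferon list had medians of -0.30 without and -0.13 after irradiation in KO against WT cells, with 0 members past the test over all genes, and -0.23 on average. In irradiated cells alone its call was lost with an estimated correlation (adjusted p = 0.73) and without irradiated WT array 1 (0.13). For the average a single array is argued against, since the highest median with 1 array left out was -0.14 and the call held each time. Fewer plasmacytoid or dendritic cells in the KO samples stay open as well. Their marker list had a median of 0.12 and a mean of 0.11 (SE of the mean 0.044). Its scores were highest in the arrays with high B cell markers, 0.38 in untreated KO array 2 and 0.16 in irradiated KO array 3. The other KO arrays had -0.16 to -0.04, and none lay below the WT arrays of its dose (-0.08 to 0.14 untreated, -0.19 to -0.06 irradiated). The median and mean met the bound against this source, which was written after the results were seen. The list may however follow those B cell markers, and the bound was not tested without these arrays, so it cannot decide this. Fewer T or NK cells stay open, although the sort removed CD3, CD4 and CD8a: their list had a median of 0.0080 and a mean of -0.03 (SE 0.111). Of its brightest members, Nkg7 had 0.16 and Ccl5, also in the NF-kB list, -1.03, with 9.68 to 10.14 in KO and 10.31 to 11.38 in WT arrays. Of 100 splits within dose, 2 had a median as far from 0 (real -0.23, the other -0.31). This met the bound set beforehand against variation between samples, but that bound was judged insufficient after the result was seen. It counts each array as independent, whereas WT arrays with the same number correlate with r = 0.42 to 0.49. Levels of the sex-linked Xist and Uty also match between the doses, in KO cells with the numbers 2 and 3 crossed, which points to pools shared by both doses. In that case 6 pools give 10 splits and no share under 0.05. Variation between pools shared by these genes, fewer plasmacytoid, dendritic, T or NK cells and an effect of NIPA therefore cannot be told apart. Camera with an estimated correlation gave adjusted p = 0.18.

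The antioxidant score, which holds Slc7a11, Hmox1 and Srxn1, lay above the untreated group mean by less in the irradiated arrays numbered 1, by 0.19 against 0.97 in WT and 0.33 against 1.04 in KO cells. Taken from the untreated array with the same number, which pairs the WT arrays, the rise in WT was 0.28 against 0.74 and 1.11, a share of 0.308. In KO cells it was 0.56 against a mean of 0.92, a share of 0.602. KO arrays 1 correlated between the doses at 0.47, and crossing the numbers 2 and 3 leaves that mean unchanged. A weaker response of all genes as the whole cause is argued against, since p53 targets in these arrays rose by shares of 0.879 and 0.843 of those in arrays 2 and 3, where the antioxidant shares were 0.191 and 0.321. From the same-numbered arrays the p53 shares were 0.869 and 0.900, against antioxidant shares of 0.308 and 0.602. From the group means the shares of NF-kB (1.27 and 1.10) and G2/M genes (1.12 and 1.23) were above 1. A weaker response of part of the genes stays open: component 1 was 15.4 and 7.13 in irradiated WT and KO array 1, against 19.9 and 28.4 in WT and 29.3 and 27.3 in KO arrays 2 and 3, and Mir34a was 7.29 and 7.26 against 8.93 to 10.33. A batch shared by arrays of the same number may be the source, but the score of untreated KO array 1 lay -0.34 from the other untreated KO arrays and that of untreated WT array 1 -0.15 from its own, inside the untreated WT range of 0.50. It therefore cannot be told apart from spread between samples. The design gives no group for these arrays, and no biological explanation was tested.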

How the results depend on the processing

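Leaving out the irradiated arrays numbered 1 and leaving out untreated KO array 2 with irradiated KO array 3 were chosen after seeing the data. So were the list tests with the block within genotype and with array medians subtracted, while the other alternatives were chosen before. Of 303 results for named genes, Fancd2, Cdkn1a and Plk1 among them, 0 reversed under 23 alternatives, 45 lost a call somewhere and 18 gained one. Of 150 list results under 22 alternatives, 52 lost a call somewhere, 40 gained one and 13 reversed. A reversal was counted only where the gene or list was called in the main fit or in the alternative. The gene count for genotype averaged over doses was 2 with the 60th percentile, array weights, the mean over probe sets or an adjusted p of 0.1, and 4 with the replicate block. The WT irradiation count was 1228 with the block within genotype, 1286 at an adjusted p of 0.1, 1147 without the irradiated arrays numbered 1, and 314 to 1040 with single arrays left out. In KO cells it was 1647 with array weights, 1390 with the block within genotype, 1499 at an adjusted p of 0.1, 557 with only the arrays compared, 1702 without the irradiated arrays numbered 1, 283 without the arrays with high B cell markers and 392 to 1573 with single arrays left out. For irradiation on average it was 1024 at 1.5-fold or more and 1403 without the arrays with high B cell markers. Fewer arrays or a looser threshold account by construction for part of this, and otherwise the cause was not tested. The same number did not mark the nearest array in KO cells: untreated KO array 2 correlated best with irradiated KO array 3 (r = 0.44) and untreated 3 with irradiated 2 (0.52), while the numbers 1 correlated at 0.47, so the block is no pairing there, nor between the irradiated groups (r = -0.29 to 0.34). Xist and Uty levels matched the same arrays of KO cells, but no fit with these crossed pairs was run. With the replicate block the interaction lost the granulocyte list (adjusted p = 0.052) and gained mast cell markers (0.022), and the interaction gene count of 0 comes from a fit without pairs.

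Lists called numbered 2, 2, 0, 0 and 0 with an estimated correlation (WT and KO irradiation, genotype untreated and irradiated, interaction), and 11, 11, 0, 0 and 0 by fry. The interaction had 5 with loess. Without the arrays with high B cell markers they numbered 6, 2 and 5 for genotype untreated, genotype irradiated and interaction, and with single arrays left out 5 to 16, 1 to 12 and 2 to 14. Medians that turned sign with single arrays left out ranged, for genotype in untreated cells, from -0.014 to 0.20 (homologous recombination, Atm), -0.45 to 0.022 (aged stem cell) and -0.21 to 0.050 (immediate early, Dusp4). In irradiated cells the ranges were -0.16 to 0.12 (oxidative phosphorylation), -0.078 to 0.14 (p53 targets), -0.016 to 0.18 (ribosome biogenesis, Heatr1) and -0.0047 to 0.18 (G1/S, Cdc6), with -0.16 to 0.24 for granulocyte markers, while haematopoietic stem cell genes stayed below 0 (-0.33 to -0.031). In the interaction they were -0.082 to 0.51 (granulocyte), -0.047 to 0.24 (oxidative phosphorylation), -0.25 to 0.25 (monocyte) and -0.040 to 0.33 (G2/M, Prc1). Without the irradiated arrays numbered 1 the tested direction turned, with medians in irradiated cells of -0.024 (G1/S), -0.038 (haematopoietic stem cell), -0.17 (oxidative phosphorylation) and -0.32 (granulocyte), and in the interaction of -0.045 (oxidative phosphorylation) and -0.22 (granulocyte). Without the arrays with high B cell markers the immediate early list had 0.050 in untreated and G1/S -0.0047 in irradiated cells. The cause was not tested. Signal near background limits dim genes, of which 6832 were not tested.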

Other observations

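The groups and genes below and the test of neighbours were chosen after the values were seen. Camera was run on 10 groups, of which some are not described, and adjusted over them. After irradiation none was called with an estimated correlation, with adjusted p of 0.072 or more in WT and 0.10 or more in KO cells. Of all 15348 genes tested, 327 rose and 415 fell by limma in WT and 420 rose and 491 fell in KO cells. Mitochondrial ribosomal proteins had medians of -0.34 in WT and -0.26 in KO cells after irradiation over 71 genes, of which 4 and 1 fell by limma, with Mrpl42 at -1.14 and Mrpl23 at -0.68 in WT (camera adjusted p = 9.1e-12 and 8.2e-06, adjusted p = 0.29 and 0.50 with an estimated correlation). Of 64 small nucleolar RNAs 3 fell in WT and 2 in KO cells, with Snord92 at -1.11 in WT and Snora75 at -1.32 in KO cells (camera adjusted p = 0.14 and 0.13 with an estimated correlation). Counts this small, beside those of all genes, say little about the group. Of 27 TNF ligands and receptors 4 rose in WT, and 6 rose and 1 fell in KO cells, with Tnfrsf23 at 0.84 and 1.08 and Tnfrsf1b at 0.64 and 0.54. Of 18 Eph receptors and ephrins, Epha2 and Efnb2 (1.21 and 1.53) rose in both. Chemokines that rose in both included Ccl3 (0.84 and 1.23). Mir34a, among the 8 largest rises in KO cells, had 2.54 in WT.

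Sex-linked genes differed between pools. Xist had log2 values of 11.20, 4.83 and 11.44 in untreated WT arrays 1 to 3, 11.35, 5.19 and 11.45 in irradiated WT, 9.21, 11.28 and 5.37 in untreated KO and 8.69, 5.46 and 11.23 in irradiated KO arrays. The Y-linked Uty had 4.72, 8.25 and 6.57, then 4.37, 8.41 and 6.73, then 8.04, 7.20 and 8.38, then 8.09, 8.40 and 7.50. In WT, both genes matched between untreated and irradiated arrays of the same number. In KO cells untreated arrays 1, 2 and 3 matched irradiated arrays 1, 3 and 2. This points to pools shared by both doses, which the labels do not state. Among B-lineage genes, Igll1 had 9.56 in untreated KO array 2 and 9.96 in irradiated KO array 3 and 7.76 or less elsewhere, and Ebf1 9.51 and 9.62 and 7.42 or less elsewhere. The myeloid gene Cybb had 9.13 in untreated KO array 1 and 9.86 in irradiated KO array 1 and was lower in all others.

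A hypothesis was that DNA flanking Zc3hc1, kept from the strain in which the gene was changed, alters genes next to it. Of the 40 nearest tested genes, 20 on each side, 2 had an unadjusted limma p under 0.05 for the average genotype effect, where 1.65 would be expected from the 4.13% of all genes. The exact hypergeometric p was 0.496, and the largest difference was 0.32. None was a member of the interferon list. The test leaves the hypothesis open, since few genes next to a locus need differ.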
